A study of Mus musculus with 12 samples.

How the data were processed

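The material was poly(A) RNA from bone marrow cells of C57BL/6 mice that had been sorted by flow cytometry as lineage-negative, Sca-1-positive and Kit-positive (LSK), the fraction that holds blood stem cells and the earliest multipotent progenitors. Per the labels' protocols, 10 to 20 ng of total RNA were amplified with an oligo-dT template-switching kit (SMARTer) and made into libraries by transposase tagmentation (Nextera). Such kits do not mark the strand of a transcript. The 12 libraries fall into 4 groups of 3 by the genotype in the labels. These are Vav Cre alone (the control), a human KDM6B transgene under the Vav promoter (KDM6B OE), Vav Cre with both Tet2 alleles floxed (Tet2 KO), and the transgene with Vav Cre and floxed Tet2 (double lesion). The label of the KDM6B OE group names no Cre. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

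Per the submitters' processing notes, reads were handled with TopHat2 2.0.10, HTSeq 0.6.0 and edgeR 3.8.6 on the mouse build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here. The deposited table held 15366 genes and 1 column per library, in a signal unit that comes from counts divided by a size factor. Each value was a whole number of reads divided by an effective library size, that is, a CPM value (the count over the scaled library total) after the authors' edgeR scaling. All values gave back whole reads (100% within a tolerance of 1e-06 reads). The column totals therefore ran from 947374 to 1076728 rather than being equal. No gene had fewer than 10 reads over the 12 libraries, so genes under that level had already been left out.

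The reads recovered on the listed genes came to 23140462 to 23536544 in Vav Cre, 22256354 to 25922064 in KDM6B OE, 21935022 to 25365202 in Tet2 KO and 25102856 to 26263370 in the double lesion. A single read was worth 0.0373 to 0.0463 CPM, and 3 reads, the limit that a count of 0 allows, were worth at most 0.139 CPM. Reads carry no molecular identifiers, so this limit covers counting error only. The 10 most abundant genes took 3.10% to 4.10% of the reads. Replicates differed by far more than sampling noise (chi-square per gene between replicates of a group from 18.9 to 98.5), so each library was counted once.

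Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (an empirical Bayes fit with a mean trend), on genes with a CPM above 1 in at least 3 libraries. That left 13046 genes and set aside 2320. The model had 1 mean per group, no covariate and 8 residual degrees of freedom, and all 12 libraries shared 1 estimate of the spread. Fold changes are log2 differences on the log2(CPM + 1) scale, which understates the change of genes with low values. Adjusted p-values are limma's with Benjamini-Hochberg adjustment within a comparison, and a gene was called changed at an adjusted p under 0.05. The comparisons were each single lesion and the double lesion against Vav Cre, the double lesion against each single lesion, and the interaction (the double lesion minus both single lesions plus Vav Cre). Tet2 and Kdm6b were also compared by exact two-sided permutation tests of CPM; with 3 libraries against 3 the smallest p is 0.1. The design had foreseen plain CPM as the unit; the test it names was kept, since it fits values divided by a size factor.

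A set of 33 gene lists was fixed in advance, of which 32 could be tested with at least 3 members; the list of mitochondrially encoded transcripts had too few tested genes. Lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. List p-values were adjusted by Benjamini-Hochberg over the 32 lists of a comparison. With the preset correlation, 9, 13, 14, 19, 10 and 8 lists were called in the order of the comparisons above. With an estimated correlation, 0, 0, 0, 0, 1 and 0 calls held, and fry called 4, 0, 9, 0, 2 and 0 lists. Intervals of list medians are 95% bootstrap intervals over genes (2000 draws), and genes are not independent replicates.

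The scripts were tested on simulated data. For the double lesion against Vav Cre 12903 genes were run, each drawn independently of the others. The limma step recovered 22.9% of genes changed 1.5-fold, 43.8% of those changed 2-fold, 87.8% of those changed 4-fold and 91.5% of those changed 8-fold, with 4 false calls. Genes of the real libraries share variation, so this number of false calls may be too low for them. With permuted residuals and no change, 3 of 100 draws made calls in this comparison, up to 2458. On data without any change, camera with the preset correlation called on average 8.66, 8.64, 8.64, 8.64, 8.66 and 8.98 of 32 lists in the 6 comparisons (50 draws). With an estimated correlation the averages were 0, 0, 0, 0, 0.02 and 0, and with fry 0.22, 0, 0.06, 0.1, 0.36 and 0.16. A list call with the preset correlation alone is thus weak evidence, and each is given with its p under an estimated correlation.

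Named genes follow a fixed rule. It takes Tet2 and Kdm6b; for each comparison up to 12 genes in each direction with the largest fold change among called genes whose groups do not overlap, leaving out gene models without a proper symbol; the 4 with the smallest p where fewer than 4 passed; and up to 4 members per described list with the smallest p. A few genes outside it are named as chosen after their values were seen. A few that the rule gives are not reported here. The groups, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were another pseudocount (0.25), no filter, a mean of at least 5 CPM, rescaling to equal totals or by median-of-ratios factors, the replicate number as a block, array weights, only the compared groups in the fit, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. A sex term and a correction of each library for transcript length and GC content were added after seeing the data.

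Symbols were matched to the GENCODE M21 annotation of GRCm38 (mm10), which gave 14772 matches and 594 without one. Coordinates are from that annotation and count from 1. Where exons overlap those of another gene, or where family members are nearly identical (replication-dependent histone genes, Ear genes), the value of a single gene is uncertain. Priming with oligo-dT takes up transcripts with a poly(A) tail, so the values do not cover histone transcripts without one. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.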

Results

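RNA was measured in sorted LSK cells, the bone marrow fraction with blood stem cells and multipotent progenitors, from mice with a human KDM6B transgene, with deletion of Tet2, with both lesions or with Vav Cre alone. Each of the 4 groups had 3 libraries, with 21935022 to 26263370 reads on listed genes per library. KDM6B removes methyl groups from lysine 27 of histone H3. TET2 oxidises methylated cytosine in DNA, and Vav sequences direct expression to blood cells. Values are CPM as mean ± SD (n = 3 per group) or log2 fold changes ± SE on the log2(CPM + 1) scale, with limma's adjusted p. Sex differed between libraries and the labels do not give it. Transcripts of the Y chromosome (mean of 4 genes 58.2 to 67.5 CPM) were present in Vav Cre 1, Tet2 KO 1 and double lesion 1 and 3. The other 8 libraries had at most 0.355 CPM of them and 312 to 462 CPM of Xist.

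The targeted genes were read first, as a check of the labels. Tet2 (chromosome 3, 133463679 to 133545139, GRCm38; its exons overlap Gm42567 on the opposite strand) stood at 82.1 ± 15.5 CPM in Vav Cre and 79.0 ± 12.3 CPM in KDM6B OE. It was at 26.8 ± 4.10 CPM in Tet2 KO, 32.7% of Vav Cre (exact permutation p = 0.1). It was at 32.9 ± 5.70 CPM in the double lesion, 40.1% of Vav Cre (exact permutation p = 0.1). Each of the 6 libraries with floxed Tet2 lay below each of the 6 without, at 37.1% of their mean (exact two-sided permutation p = 0.00216). In limma, Tet2 fell by 1.57 ± 0.18 in Tet2 KO (adjusted p = 0.00904) and by 1.29 ± 0.18 in the double lesion (adjusted p = 0.00315). The Tet2 KO call ended with only the compared groups in the fit (adjusted p = 0.225). The count covers the whole gene, exons outside the floxed part included. Mouse Kdm6b (chromosome 11, 69398508 to 69413675, with Kdm6bos on the opposite strand) was at 6.94 ± 0.844 CPM in Vav Cre, 10.2 ± 2.37 CPM in KDM6B OE, 6.04 ± 0.758 CPM in Tet2 KO and 10.5 ± 1.61 CPM in the double lesion. The 6 libraries with the transgene averaged 1.60 times the 6 without it (exact two-sided permutation p = 0.00433). Single comparisons of Kdm6b did not pass. The log2 difference from Vav Cre was 0.48 ± 0.22 in KDM6B OE (adjusted p = 0.217) and 0.53 ± 0.22 in the double lesion (adjusted p = 0.107). With the length and GC trend removed per library, an alternative chosen after seeing the data, both were at 0.16 (adjusted p = 0.731 and 0.660). Reads were aligned to a mouse genome, so the human transgene was not measured as such, and reads that it might share with Kdm6b were not told apart.

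**Figure D1:**
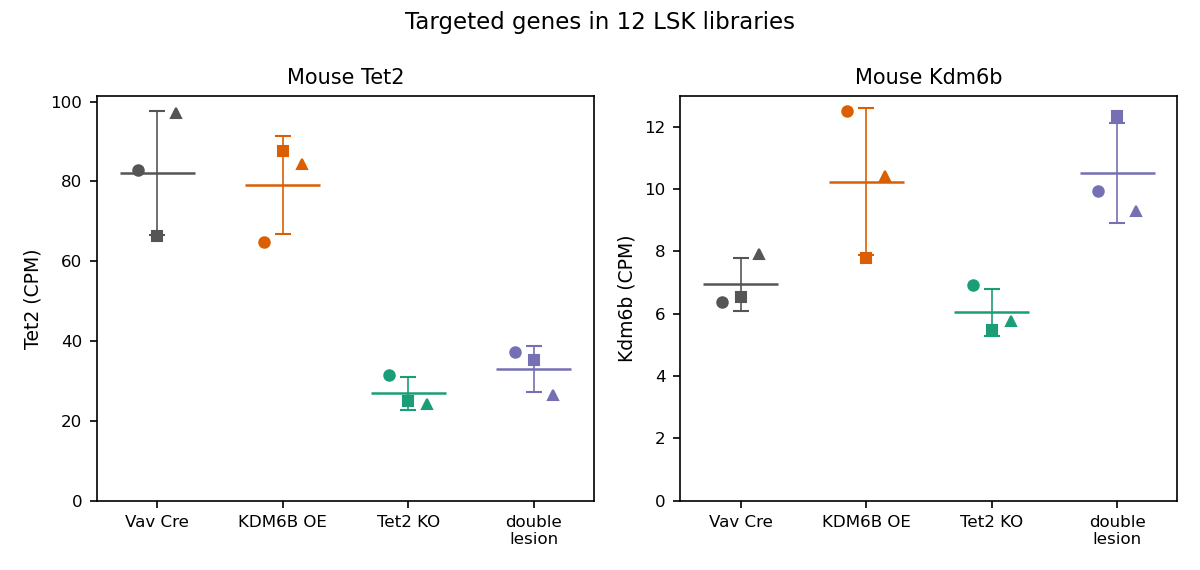
Tet2 and Kdm6b in CPM for each of the 12 libraries (points), with bars at the group mean and error bars of 1 SD (n = 3). Tet2 lies at 24.1 to 37.2 CPM in the 6 libraries with floxed Tet2 and at 64.9 to 97.1 CPM in the others, and Kdm6b is at 7.79 to 12.5 CPM with the transgene and at 5.46 to 7.91 CPM without it.

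KDM6B OE against Vav Cre asks what goes with the transgene alone. The groups also differ in Cre, since only the control is labelled with it. The clearest difference was in immediate early genes, which cells switch on within minutes of a stimulus and also during tissue dissociation. Of 30 members tested, 19 rose and none fell. All 30 had a positive value, with a median of 1.59 (95% interval 1.43 to 2.14). Fos (chromosome 12, 85473890 to 85477273), a subunit of the AP-1 transcription factor, rose from 102 ± 69.6 to 1271 ± 494 CPM (3.75 ± 0.69, adjusted p = 0.0307). Egr1 (chromosome 18, 34859823 to 34864984), a zinc finger transcription factor, rose from 38.4 ± 21.1 to 378 ± 165 CPM (3.34 ± 0.39, adjusted p = 0.00154). The Krüppel-like factors Klf2 (chromosome 8, 72319033 to 72321656) and Klf6 (chromosome 13, 5861482 to 5870394) rose from 6.54 ± 2.89 to 84.3 ± 15.5 CPM and from 110 ± 12.9 to 711 ± 168 CPM. Their log2 changes were 3.57 ± 0.47 (adjusted p = 0.00328) and 2.66 ± 0.22 (adjusted p = 0.000175). Dusp1 (chromosome 17, 26505590 to 26562128, overlapped by Ergic1), a phosphatase of MAP kinases, rose by 2.84 ± 0.34. Zfp36 (chromosome 7, 28376784 to 28380253, overlapped by Gm44710), which destabilises inflammatory mRNAs, rose by 2.59 ± 0.32. Atf3, Jund, Ppp1r15a and Junb, all in this list, rose by 2.79 ± 0.50, 2.16 ± 0.40, 2.12 ± 0.40 and 1.88 ± 0.20. The small early genes Ier5 and Ier2 rose by 1.46 ± 0.13 and 1.57 ± 0.17. The list passed in camera (adjusted p = 2.1e-25; adjusted p = 0.103 with an estimated correlation) and fry (adjusted p = 0.000658). In all, 26 members passed when adjusted over the list alone. Heat-shock genes, a set put together after the result was seen, had a median of 0.47 (95% interval −0.16 to 1.21) over 8 genes. Hspa1a, Hspa1b and Dnajb1 (1.53, 1.32 and 1.10) are also in the immediate early list, and Hsp90aa1, Hspe1 and Hspd1 were at −0.33, −0.27 and −0.05.

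**Figure D2:**
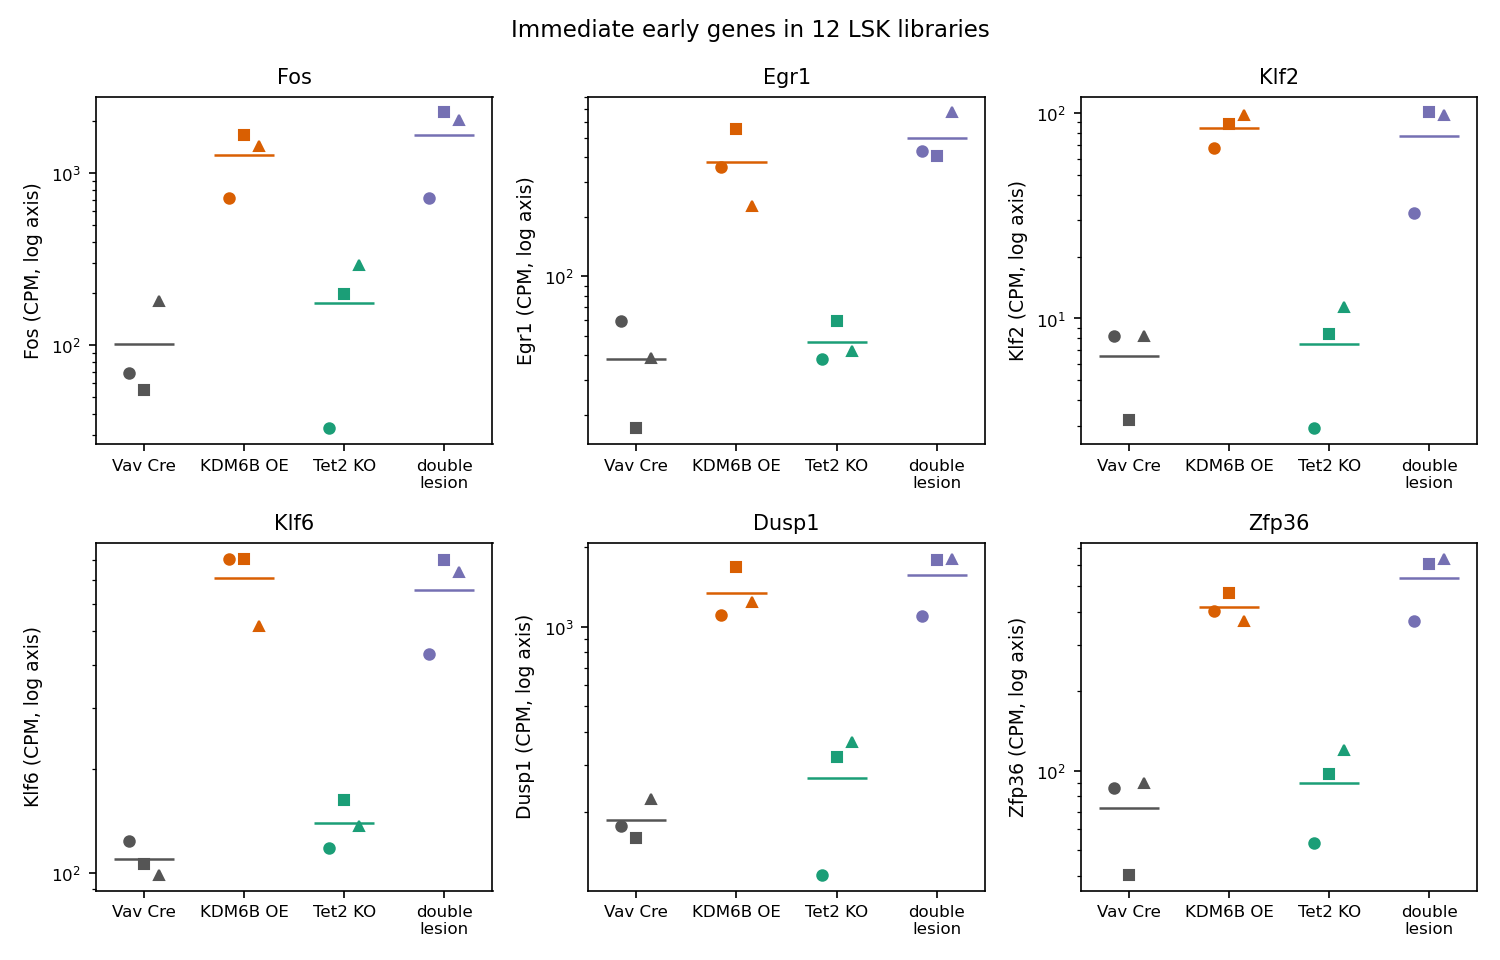
CPM (log axis) of Fos, Egr1, Klf2, Klf6, Dusp1 and Zfp36 in each library of the 4 groups, with a horizontal line at the group mean. Klf6, for example, averaged 711 CPM in KDM6B OE and 656 CPM in the double lesion, against 110 CPM in Vav Cre and 139 CPM in Tet2 KO.

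Outside that list, the chemokine Ccl4 rose from 26.3 ± 10.3 to 122 ± 59.7 CPM in KDM6B OE (2.13 ± 0.29, adjusted p = 0.00493). Rgs1, a brake on G protein signalling, rose from 101 ± 28.1 to 412 ± 131 CPM (2.01 ± 0.25, adjusted p = 0.00221). Ccl4 belongs to the innate immune and NF-kB list, in which 3 of 35 members rose, among them Nfkbiz (1.86 ± 0.27), a nuclear IkB protein. That list had a median of 0.29 (adjusted p = 0.000683; adjusted p = 0.262 with an estimated correlation), and 9 members passed when adjusted over the list alone. Among p53 targets and apoptosis genes 2 of 28 rose, the survival gene Mcl1 (0.83 ± 0.11) and the antiproliferative gene Btg2 (1.44 ± 0.21). Btg2 is also a member of the immediate early list. In that list 8 passed when adjusted over the list alone (median 0.31, or 0.18 without Vav Cre 2; adjusted p = 0.000683; adjusted p = 0.262 with an estimated correlation). Of 40 interferon response genes none passed, with a median of 0.29 (adjusted p = 0.0185; adjusted p = 0.892 with an estimated correlation) and 0 when adjusted over the list alone. Without Vav Cre 3 the numbers that rose were 7 innate immune, 6 p53 and 5 interferon genes. Without Vav Cre 1 it was 5 innate immune genes, and without Vav Cre 2 it was 2 innate immune genes and 1 interferon gene.

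Lower genes were fewer. Il1rl1, the receptor of interleukin 33, fell from 9.61 ± 2.26 to 2.35 ± 0.616 CPM (−1.66 ± 0.26, adjusted p = 0.0095). Scin, an actin-severing protein, fell from 13.8 ± 3.35 to 3.90 ± 1.81 CPM (−1.63 ± 0.26, adjusted p = 0.0111). The histone genes Hist2h2bb (−1.59 ± 0.23), Hist1h2bp (−1.33 ± 0.27), Hist1h3g (−1.27 ± 0.26) and Hist1h2be (−1.22 ± 0.24) fell. Each is uncertain because of near-identical copies or overlapping genes, and oligo-dT priming does not cover histone transcripts without a poly(A) tail. Cdca3, a mitotic entry factor, fell by 0.73 ± 0.14, the condensin subunit Smc2 by 0.67 ± 0.14 and the cohesin subunit Smc3 by 0.46 ± 0.09. In the replication-dependent histone list 2 of 30 members fell (median −0.70, adjusted p = 5.3e-11; adjusted p = 0.262 with an estimated correlation), with 18 lower and 1 higher when adjusted over the list alone. The G2 and M phase list had a median of −0.42, with 1 of 40 members past the test and 19 adjusted over the list alone. Its member Smc4 was at −0.52 ± 0.13 (adjusted p = 0.0903). No gene of the ribosomal protein list (63 genes, median −0.46) or of the nuclear-encoded respiratory chain list (41 genes, median −0.34) passed over all genes in limma, against 60 and 16 adjusted over the list alone. Examples are Rps20 at −0.51 ± 0.14 (adjusted p = 0.104) and Cox5a at −0.50 ± 0.14 (adjusted p = 0.111). These 3 lists had adjusted p = 0.585 with an estimated correlation. S phase genes had a median of −0.12 (adjusted p = 0.014; adjusted p = 0.892 with an estimated correlation), with 0 of 36 past the test and 0 adjusted over the list alone. Without Vav Cre 2 the ribosomal median was −0.29, the respiratory chain median −0.17 and the S phase median −0.08. The S phase median was −0.07 without KDM6B OE 1 and −0.18 without KDM6B OE 3. Without Vav Cre 3, 55 ribosomal, 15 respiratory chain, 15 G2 and M phase and 12 histone genes fell, and for S phase 1 rose and 2 fell. Of the histone genes 5 fell without Tet2 KO 2, 0 without KDM6B OE 1 and 1 without any 1 of the others. The G2 and M phase count was 3 without double lesion 1 and 0 without any 1 of Vav Cre 1 and 2, KDM6B OE 1 and 2, Tet2 KO 3, and double lesion 2 and 3.

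In total 78 genes changed in KDM6B OE, 68 higher and 10 lower, of which 49 by 2-fold or more. edgeR on the recovered reads called 78 and DESeq2 729. The replicate block, array weights and a sex term also gave more than 78, as listed under the dependence on processing. The groups did not overlap for 22.6% of genes, where chance gives 10% on average. Genes are not independent, so without any change such a share may lie far from 10%. No range was computed for it in any comparison. Ier5, Ier2, Klf2, Klf6, Egr1, Dusp1, Zfp36, Junb, Rgs1 and Btg2 kept their call under every alternative. With only the compared groups in the fit 22 genes passed, and the calls of Atf3, Jund, Ccl4, Nfkbiz, Mcl1, Il1rl1, Scin, Cdca3, Smc2, Smc3, Hist1h2bp, Hist1h3g and Hist1h2be ended (adjusted p from 0.0571 to 0.199). Jund, Hist1h2bp and Hist1h3g were also lost in edgeR (adjusted p = 0.0598, 0.0566 and 0.0561), and Hist1h2bp and Hist1h3g with the trend on length and GC removed (0.0633 and 0.0510). Without a filter Hist1h2be, Hist1h3g, Smc2 and Smc3 were lost (0.0541 to 0.0582), and Hist1h3g with a pseudocount of 0.25 (0.0526) or rescaled to equal totals (0.050). The control libraries spread most, with a median SD of 0.28 on the log2 scale against 0.15 in KDM6B OE, and the count depended on single libraries. It was 1934 without Vav Cre 3 and 143 without Tet2 KO 2. It was 43 without Vav Cre 2, 22, 24 and 47 without KDM6B OE 1, 2 and 3, 50 without Tet2 KO 3, and 36 without double lesion 2 or 3. The call of Fos ended without Vav Cre 1 or 2, any 1 KDM6B OE library, or double lesion 2 or 3 (adjusted p up to 0.162). Jund and Ppp1r15a were lost without Vav Cre 1 or 2, KDM6B OE 1 or 2, or double lesion 2 or 3 (up to 0.162 and 0.174), and Atf3 without Vav Cre 1 or 2, KDM6B OE 1 or 2, or double lesion 2 (up to 0.141). Scin was lost without KDM6B OE 2 (0.0882) or 3, and Hist2h2bb without KDM6B OE 1 (0.0511). Cdca3 was lost without Vav Cre 1 or 2, KDM6B OE 1 or 2, Tet2 KO 3, or double lesion 2 or 3 (up to 0.193). Smc2, Smc3, Hist1h2bp, Hist1h3g and Hist1h2be were lost without any 1 of Vav Cre 1 and 2, the KDM6B OE libraries, Tet2 KO 1 and 3, and double lesion 2 and 3 (up to 0.211). All of these but Smc2 were also lost without double lesion 1. The count of immediate early genes that rose was 12 without Vav Cre 2, KDM6B OE 1 or KDM6B OE 2.

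Tet2 KO against Vav Cre asks what Tet2 loss alone goes with, both groups carrying Cre. Besides Tet2, 3 genes changed, all higher. Fgf3 (chromosome 7, 144838083 to 144844436), a fibroblast growth factor, rose from 9.42 ± 2.59 to 27.2 ± 0.964 CPM (1.47 ± 0.21, adjusted p = 0.0338). Pramef8 (chromosome 4, 143412426 to 143421091), of the PRAME gene family, rose from 23.7 ± 1.79 to 46.4 ± 3.08 CPM (0.94 ± 0.13, adjusted p = 0.0337). Trim12c (chromosome 7, 104338754 to 104353362, overlapped by Gm27995), of the tripartite motif family, rose from 27.1 ± 1.01 to 52.1 ± 3.91 CPM (0.92 ± 0.14, adjusted p = 0.0338). Among lower genes Slc7a1, a cationic amino acid transporter, was at −0.81 ± 0.14 (adjusted p = 0.0597), Socs2, a suppressor of cytokine signalling, at −1.03 ± 0.20 (adjusted p = 0.134) and Il1rl1 at −1.27 ± 0.26 (adjusted p = 0.134).

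Of 40 interferon response genes in Tet2 KO, 36 had positive values with a median of 0.54. None passed over all genes, and 12 passed when adjusted over the list alone (adjusted p = 1.9e-11; adjusted p = 0.568 with an estimated correlation). Oasl2 (0.68 ± 0.11, adjusted p = 0.0597) and Ddx58 (0.57 ± 0.12, adjusted p = 0.152), which act in antiviral defence, are examples. Of these genes 2 rose without Vav Cre 3, and 1 without Vav Cre 2, KDM6B OE 3 or Tet2 KO 1. The monocyte and macrophage list had a median of 0.39 with 27 of 31 members positive (adjusted p = 0.00181; adjusted p = 0.613 with an estimated correlation), and Cybb, a subunit of the phagocyte oxidase, was at 1.70 ± 0.53 (adjusted p = 0.246). That median was 0.21 without Vav Cre 1, 0.66 without Tet2 KO 1 and 0.15 without Tet2 KO 3. The neutrophil granule list (24 genes, median 0.29, 5 adjusted over the list alone) included S100a9 at 0.365 against 4.21 CPM (adjusted p = 0.167). Its median ranged from 0.11 without Tet2 KO 3 to 0.64 without Tet2 KO 1. It was 0.17, 0.51 and 0.47 without Vav Cre 1, 2 and 3. In the antigen presentation list (20 genes, median 0.21, 3 adjusted over the list alone) the MHC class II gene H2-Aa was at 1.14 ± 0.34 (adjusted p = 0.239) and the invariant chain Cd74 at 1.14 ± 0.42 (adjusted p = 0.299). Cd74 was at 1074 CPM in Tet2 KO 2 against 317 and 255 CPM in Tet2 KO 1 and 3. The B cell genes Cd79a (49.8 against 7.29 and 3.26 CPM) and Ms4a1 (16.0 against 1.37 and 1.39 CPM) were also high in Tet2 KO 2. H2-Aa was not set apart there (117 against 135 and 94.9 CPM). The antigen presentation median was 0.32 without Vav Cre 1, and 0.14 without Vav Cre 3 or Tet2 KO 2. Both lists had adjusted p = 0.568 with an estimated correlation, as did the innate immune, TGF-beta and p53 lists with medians of 0.30, 0.24 and 0.16. Without Vav Cre 2 these 3 medians were 0.20, 0.12 and 0.10, and the p53 median was 0.08 without Vav Cre 1 and 0.24 without Tet2 KO 1.

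Lower on the whole in Tet2 KO were the ribosomal protein list (median −0.39, all 63 values negative, 48 adjusted over the list alone) and the replication-dependent histone list (median −0.56, 29 of 30 negative). Examples are Rps13 at −0.51 ± 0.14 (adjusted p = 0.224) and Hist1h3g at −0.88 ± 0.26 (adjusted p = 0.239). Both had adjusted p = 0.568 with an estimated correlation. The G2 and M phase and respiratory chain lists both had a median of −0.28 and the S phase list one of −0.15, with adjusted p = 0.613 with an estimated correlation in all 3. The checkpoint gene Clspn was at −0.56 ± 0.15 (adjusted p = 0.224). The MYC target list had a median of −0.13 (adjusted p = 0.724 with an estimated correlation). It was −0.20, −0.06 and −0.08 without Vav Cre 1, 2 and 3, and −0.06 without Tet2 KO 1. The immediate early list was not called (median 0.23, 21 of 30 positive, adjusted p = 0.0802). No member of the other 6 lists in this paragraph passed over all genes in limma. Without Vav Cre 2 the ribosomal and respiratory chain medians were −0.21 and −0.12, and without Tet2 KO 2 the S phase median was −0.04. Without Vav Cre 3, 4 histone and 2 ribosomal genes fell. In this comparison 4 genes changed (edgeR 4, DESeq2 160), and 1760 had an unadjusted p under 0.05. The groups did not overlap for 12.6% of genes, where chance gives 10% on average. The count was 307 without Vav Cre 3, 2 without any 1 Tet2 KO library, 1 without KDM6B OE 2 or any 1 double lesion library, and 0 with only the compared groups in the fit. Fgf3, Pramef8 and Trim12c were lost without Vav Cre 2, KDM6B OE 2, any 1 Tet2 KO library or any 1 double lesion library (adjusted p up to 0.231), and Pramef8 and Trim12c also without Vav Cre 1. With the replicate number as a block they were at adjusted p = 0.0558, and with only the compared groups at 0.481. Fgf3 was also lost with array weights (0.0591) and Trim12c with a sex term (0.0594).

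The double lesion against Vav Cre is the comparison that the stated design is about, the expression changes that go with both lesions together. The test called 1947 genes changed, 958 higher and 989 lower, of which 398 by 2-fold or more. Immediate early genes were again higher, with 22 of 30 members rising and none falling (median 1.73). Egr1 rose to 502 ± 148 CPM (3.8 ± 0.39, adjusted p = 0.000445), Fos to 1668 ± 832 CPM (4.06 ± 0.69, adjusted p = 0.00551), and Klf6 to 656 ± 200 CPM (2.52 ± 0.22, adjusted p = 0.000181). Ier5 rose from 16.3 to 61.4 CPM (1.85 ± 0.13, adjusted p = 1.7e-05). Klf2, Dusp1, Zfp36, Ccl4 and Ier2 rose by 3.30 ± 0.47, 3.04 ± 0.34, 2.93 ± 0.32, 2.53 ± 0.29 and 1.62 ± 0.17. The list passed in camera (adjusted p = 2.3e-17; adjusted p = 0.172 with an estimated correlation) and fry (adjusted p = 0.000824), with 25 members adjusted over the list alone. The 8 heat-shock genes had a median of 0.06 (95% interval −0.40 to 0.21).

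Some genes of eosinophils and B cells, which the sort for lineage-negative cells should exclude, were also among the largest increases in the double lesion. The fixed mast cell, basophil and eosinophil list as a whole was not called (median 0.68, adjusted p = 0.0561; adjusted p = 0.625 with an estimated correlation), with 6 of 20 members rising and 1 falling, and 8 and 2 adjusted over the list alone. The eosinophil ribonuclease gene Ear1 (chromosome 14, 43818765 to 43875517, sharing exons with Ear-ps9 and close in sequence to other Ear genes) was at 0.0599 CPM in Vav Cre and 31.0 ± 29.7 CPM in the double lesion (4.49 ± 0.69, adjusted p = 0.00377). It was at 64.9 CPM in double lesion 1 and 18.9 and 9.30 CPM in 2 and 3. The eosinophil granule gene Prg3 (chromosome 2, 84988215 to 84993886) rose from 4.25 ± 6.51 to 83.1 ± 76.2 CPM (4.34 ± 0.94, adjusted p = 0.0141). The lipoxygenase gene Alox15 rose from 0.335 ± 0.581 to 7.90 ± 3.47 CPM (2.75 ± 0.36, adjusted p = 0.00241). The IgM receptor gene Fcmr stood at 0.0288 against 6.98 ± 3.44 CPM (2.87 ± 0.76, adjusted p = 0.0267), and Cd22, an inhibitory B cell lectin, rose by 2.05 ± 0.40. The Vav Cre levels of Ear1, Fcmr and Cd22 lie under the value of 3 reads (at most 0.139 CPM), so these changes depend on the 1 CPM added before the log. Ear1, Prg3, Alox15 and Fcmr also had higher means in both single lesions than in Vav Cre. In KDM6B OE and Tet2 KO, Ear1 was at 6.70 and 5.23 CPM and Prg3 at 16.4 and 20.6 CPM. Alox15 was at 2.02 and 1.37 CPM there, and Fcmr at 1.13 ± 1.79 and 9.20 ± 13.4 CPM. Among mature B and plasma cell markers 3 of 16 rose, 3 adjusted over the list alone (median 0.69, adjusted p = 0.014; adjusted p = 0.625 with an estimated correlation). None did without double lesion 1, where Cd22 was at adjusted p = 0.0554 and Prg3 at 0.0777, and 6 rose without Tet2 KO 2. Fcmr was lost without Vav Cre 1 or 2 or any 1 double lesion library (adjusted p up to 0.12).

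Immune lists were higher as well. In the innate immune and NF-kB list 14 of 35 members rose (median 0.51), 15 adjusted over the list alone, among them Nfkbiz (1.87 ± 0.27) and Tnfaip3 (1.51 ± 0.26), a feedback inhibitor of NF-kB. The list had adjusted p = 7.3e-06, adjusted p = 0.172 with an estimated correlation and fry's adjusted p = 0.000959. Of 40 interferon response genes 11 rose and 1 fell (median 0.43), 15 and 2 adjusted over the list alone. The interferon-inducible GTPase gene Iigp1 was at 1.12 ± 0.22 (adjusted p = 0.00911). The list had adjusted p = 0.625 with an estimated correlation. In the antigen presentation list 6 of 20 rose and 2 fell (median 0.43), 10 and 3 adjusted over the list alone, with adjusted p = 0.614 with an estimated correlation. The MHC class II genes H2-Aa (chromosome 17, 34282744 to 34287823) and H2-Eb1 rose from 58.3 to 182 CPM (1.80 ± 0.34) and from 43.1 to 128 CPM (1.72 ± 0.35), and their transactivator Ciita from 2.30 to 9.31 CPM (1.69 ± 0.40). Neutrophil granule genes rose in 8 of 24 cases (median 0.64, 10 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation). S100a8 was at 0.387 against 5.83 CPM (2.06 ± 0.45) and S100a9 at 0.365 against 5.40 CPM (2.12 ± 0.46). In the monocyte list 5 of 31 rose and 1 fell (median 0.28, 7 and 1 adjusted over the list alone; adjusted p = 0.756 with an estimated correlation). Klf4 was at 2.27 ± 0.49 (adjusted p = 0.0134), a gene that the immediate early list also holds. The p53 list had 5 of 28 members rising (median 0.29, 9 adjusted over the list alone; adjusted p = 0.274 with an estimated correlation), with Mcl1 at 0.88 ± 0.11 and Btg2 at 1.68 ± 0.21. The TGF-beta list had 5 of 30 (median 0.38, 5 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation), with the SMAD repressor Skil at 1.46 ± 0.26. Counts of rising genes moved both ways when single libraries were left out. The highest were 14 for the interferon list, 11 for the neutrophil list, 9 for antigen presentation and 7 for the monocyte list. The innate count did not pass 14. Without Vav Cre 2, double lesion 1, 2 and 3 in turn, the counts were 7, 6, 8 and 8 for the innate list, 6, 3, 3 and 4 for the interferon list, and 3, 5, 3 and 3 for the neutrophil list. The latter also had 5 without KDM6B OE 2 and a median of 0.35 without Vav Cre 1. The antigen presentation list had 3, 1 and 3 without Vav Cre 2, double lesion 1 and double lesion 2, and a median of 0.25 without Vav Cre 2. The monocyte list had 2, 2, 1 and 1 without these 4 libraries, 2 without Vav Cre 1 and 3 without KDM6B OE 1 or 3. Its medians ran from 0.14 without double lesion 2 and 0.16 without Vav Cre 1 to 0.43 without double lesion 1 and 0.45 without Vav Cre 2 or 3. The p53 list had 2 without double lesion 1 or 3, 3 without double lesion 2 or Vav Cre 1, and 10 without Vav Cre 3. The TGF-beta list had 1 without Vav Cre 2 (median 0.25) or double lesion 1, 3 without double lesion 2 and 10 without Vav Cre 3. H2-Eb1 was lost without double lesion 1 (adjusted p = 0.0530). S100a9 was lost without double lesion 3 (0.0502) and Ciita without Vav Cre 2 or double lesion 1 or 2 (up to 0.0939).

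Genes of dividing cells were lower in the double lesion. Of 40 G2 and M phase genes 37 fell and none rose, with a median of −0.87 (95% interval −0.98 to −0.73). Adjusted over the list alone it was 38 (adjusted p = 3.0e-25; adjusted p = 0.348 with an estimated correlation; fry's adjusted p = 0.00442). Cdca3 (chromosome 6, 124829547 to 124833701) fell from 196 ± 28.7 to 77.9 ± 12.3 CPM (−1.32 ± 0.14, adjusted p = 0.000595). Nusap1 (chromosome 2, 119618298 to 119651244, overlapped by Oip5), a spindle protein, fell from 336 to 148 CPM (−1.2 ± 0.16, adjusted p = 0.00257), and the topoisomerase gene Top2a from 702 to 352 CPM (−1.0 ± 0.14). Cdca8, of the chromosomal passenger complex, fell by 1.09 ± 0.15, and Ube2c, a mitotic ubiquitin-conjugating enzyme whose exons overlap Tnnc2, from 296 ± 88.6 to 112 ± 31.3 CPM (−1.40 ± 0.21, adjusted p = 0.0036). The number that fell was 25 without double lesion 1, with a median of −0.66. In the S phase list 11 of 36 fell (median −0.29, 15 adjusted over the list alone; adjusted p = 0.574 with an estimated correlation), among them Clspn (−0.89 ± 0.15). In the histone list 10 of 30 fell (median −0.39, 12 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation). Hist1h2ae (−1.74 ± 0.41), Hist1h4d (−1.49 ± 0.28), Hist1h1e (−1.36 ± 0.25) and H2afz (−0.89 ± 0.16), which encodes a variant histone made outside S phase too, are examples. Values of single histone genes are uncertain. The histone list covers transcripts with a poly(A) tail only, so it cannot be read as the level of all histone mRNA. Without Vav Cre 2 and double lesion 1, 2 and 3, the S phase count was 3, 3, 4 and 6, and its median was −0.16 without double lesion 1. The histone count was 6 without Vav Cre 2 and 4 without double lesion 1, with a median of −0.22 in the latter case. Hist1h2ae was lost in both (adjusted p = 0.0617 and 0.0953).

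Genes of protein synthesis and respiration were lower too. Of 63 ribosomal protein genes 59 fell (median −0.67, 95% interval −0.69 to −0.64), 60 adjusted over the list alone. Examples are Rps2, from 1453 to 802 CPM (−0.84 ± 0.14, adjusted p = 0.00521), and Rpl29, at −0.89 ± 0.16 (adjusted p = 0.00656). The list had adjusted p = 2.3e-27, adjusted p = 0.468 with an estimated correlation and fry's adjusted p = 0.0167. The number that fell was 37 without Vav Cre 2 and 6 without double lesion 1, while the median stayed between −0.78 and −0.50. Of 41 nuclear-encoded respiratory chain genes 25 fell (median −0.52), 36 adjusted over the list alone, with adjusted p = 0.468 with an estimated correlation and fry's adjusted p = 0.027. Sdhb, of complex II, was at −0.65 ± 0.13 and Cox4i1, of cytochrome oxidase, at −0.73 ± 0.14. Both were lost without double lesion 1 (adjusted p = 0.0521 and 0.0535). The respiratory count was 0 without double lesion 1, 7 without Vav Cre 2, and 13 and 15 without double lesion 2 and 3. The medians of these lists and of the other lists called in this comparison kept their sign when the libraries were rescaled to equal totals or by median-of-ratios factors.

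The largest single decreases in the double lesion were in Cotl1, an actin-binding protein (149 ± 103 against 16.0 ± 1.01 CPM, −2.71 ± 0.71, adjusted p = 0.0265), and Cnn3, a calponin (137 ± 30.3 against 33.2 ± 9.43 CPM, −2.03 ± 0.35, adjusted p = 0.00551). Sh3d19 fell by 1.90 ± 0.45, and the annexin gene Anxa9 fell too (21.7 ± 5.94 against 5.09 ± 0.758 CPM, −1.87 ± 0.34, adjusted p = 0.00653, overlapped by Mindy1). Rnf128, a ubiquitin ligase, fell by 1.68 ± 0.28, the transporter gene Slc16a11 by 1.60 ± 0.48, Lmcd1 by 1.46 ± 0.28 and the chaperone gene Clu by 1.40 ± 0.43. Of 70 called genes followed singly in this comparison, 43 kept their call under every alternative. Cotl1 was lost without Vav Cre 1 or 2 or any 1 double lesion library (adjusted p up to 0.0994), Sh3d19 without any 1 double lesion library (up to 0.0614). Slc16a11 was lost without Vav Cre 1 or 3, KDM6B OE 1 or 2, or double lesion 1 or 2 (up to 0.145), and Clu without Vav Cre 1 or 2, any 1 KDM6B OE library, Tet2 KO 3 or any 1 double lesion library (up to 0.138). With only the 6 compared libraries in the fit, Cotl1 was at adjusted p = 0.0533, Slc16a11 at 0.0689, Clu at 0.112, Ciita at 0.0534, H2-Eb1 at 0.0516, S100a8 at 0.0569, S100a9 at 0.0514 and Hist1h2ae at 0.0664. Slc16a11 was also lost in edgeR (0.0721), and Clu when rescaled to equal totals (0.059) or unfiltered (0.0505).

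edgeR called 1652 genes in the double lesion (720 higher, 932 lower) and DESeq2 2676. The share of genes with groups without overlap was 32.8%, where chance gives 10% on average, and the excess was not tested. Rescaled to equal totals, the call was 1285 higher and 763 lower, with the median of all genes at 0.12 instead of 0.05. The count was 304 without double lesion 1, 743 and 831 without double lesion 2 and 3, 611 without Vav Cre 2, 3585 without Vav Cre 3, and 289 with only the compared groups in the fit. Genes called higher were longer and richer in GC (median exonic length 4940 bp, GC 53.2%) than those called lower (2756 bp, 49.0%) or not called (4442 bp, 49.2%). A trend on length and GC took up 23.9% of the deviation of Vav Cre 2 from the gene means, 12% of that of Tet2 KO 2 and 10.5% of that of double lesion 1, against 1.29% to 7.05% in the other 9 libraries. With that trend removed per library, a step chosen after seeing the data, 1843 genes were called, 1477 of them in both.

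**Figure D3:**
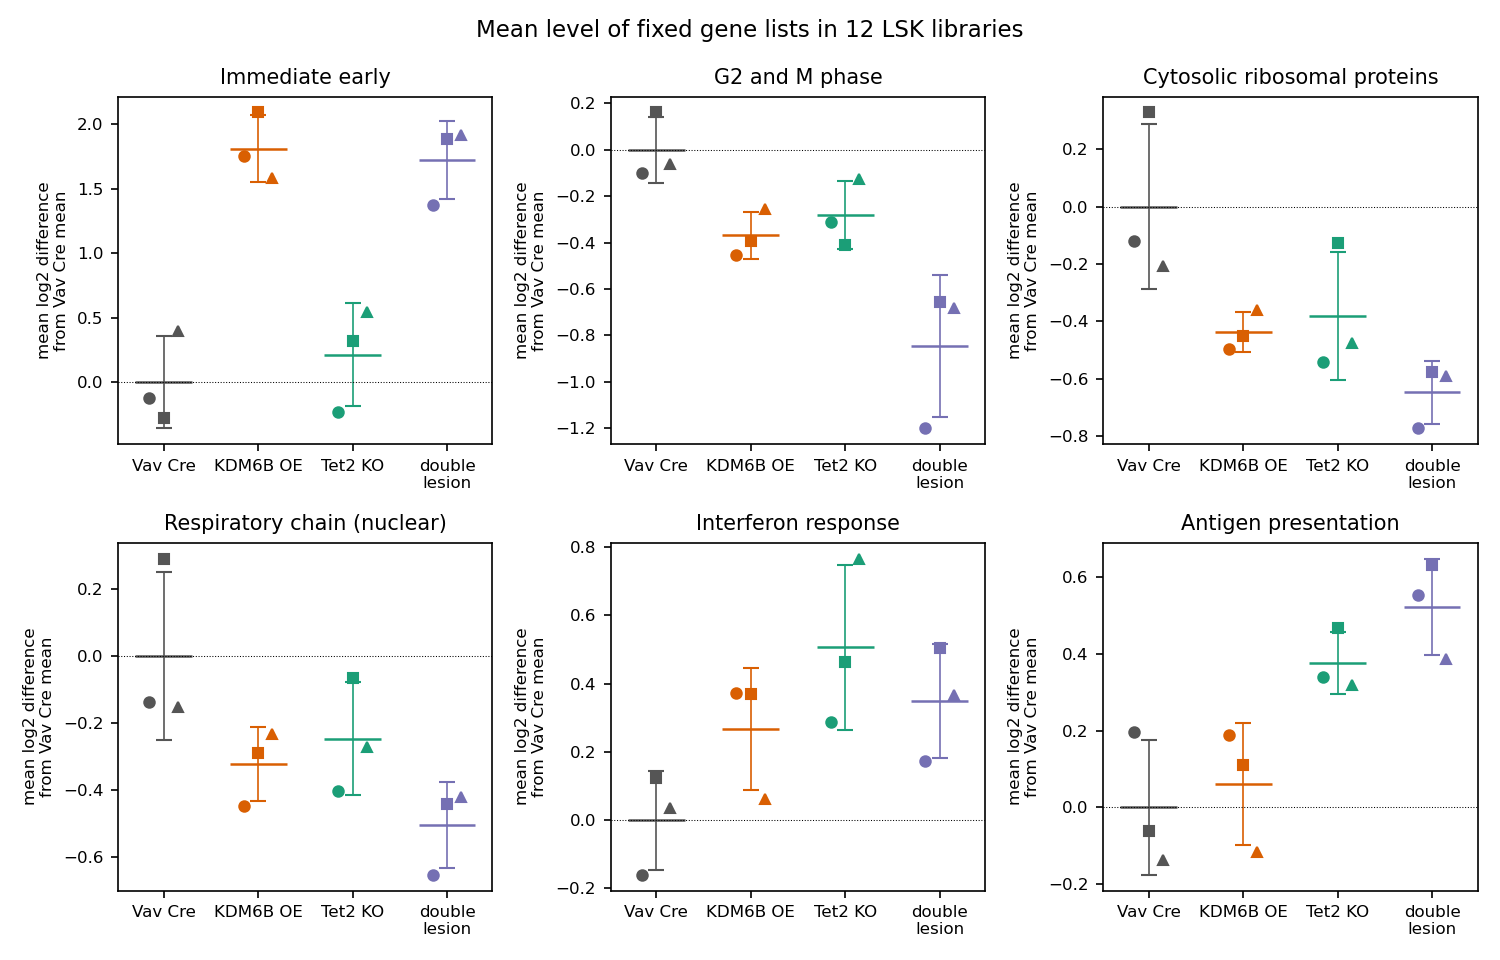
Mean log2 difference from the Vav Cre mean over the genes of 6 lists, for each library (circle, square and triangle for replicate 1, 2 and 3), with the group mean and 1 SD (n = 3). Immediate early genes average 1.81 ± 0.26 in KDM6B OE and 1.72 ± 0.30 in the double lesion against 0.21 ± 0.40 in Tet2 KO, and G2 and M phase genes average −0.37 ± 0.10, −0.85 ± 0.31 and −0.28 ± 0.15 in these groups.

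The double lesion against KDM6B OE asks what Tet2 loss, together with Cre, adds in cells with the transgene. No gene passed in limma (smallest adjusted p = 0.129) or edgeR, DESeq2 called 20, and 771 genes had an unadjusted p under 0.05. Tet2 itself was at −1.24 ± 0.18 (adjusted p = 0.129; 41.7% of the KDM6B OE level, exact permutation p = 0.1). Lpcat2 (chromosome 8, 92855339 to 92919279, overlapped by Gm45472), an enzyme of membrane lipid remodelling, was at 29.2 ± 7.44 against 68.6 ± 9.08 CPM (1.23 ± 0.19, adjusted p = 0.136). Scin was at 1.41 ± 0.26 (adjusted p = 0.278), Snx22, whose exons overlap Ppib, at 1.29 ± 0.24 (adjusted p = 0.278), and the lipid antigen presenter Cd1d1 at 0.79 ± 0.15 (adjusted p = 0.284). On the lower side Bub1, a spindle checkpoint kinase, was at 89.8 ± 3.53 against 56.4 ± 7.56 CPM (−0.67 ± 0.12, adjusted p = 0.278), Anxa9 at −1.78 ± 0.34 (adjusted p = 0.278) and Stxbp4 at −0.74 ± 0.15 (adjusted p = 0.284).

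All 40 G2 and M phase genes had lower values than in KDM6B OE, with a median of −0.50 (−0.32 without double lesion 1) and 32 past the test when adjusted over the list alone, for example the proliferation marker Mki67 at −0.55 ± 0.13 (adjusted p = 0.397). The list had adjusted p = 7.3e-29 and adjusted p = 0.207 with an estimated correlation. The immediate early list had a median of −0.04 with 15 of 30 values positive (adjusted p = 0.936). Lists of mature cells lay higher. The monocyte list had a median of 0.55 (0.35 without double lesion 2; 28 of 31 positive; adjusted p = 0.278 with an estimated correlation), with the lysosomal gene Psap at 0.69 ± 0.19 (adjusted p = 0.513). The mature B cell list had a median of 0.74 (0.45 without double lesion 3; adjusted p = 0.242 with an estimated correlation), and the mast cell, basophil and eosinophil list one of 0.84. The neutrophil granule list was at 0.36 (0.55 without double lesion 1, 0.22 without double lesion 3), the dendritic cell list at 0.28 (0.10 without double lesion 2) and the antigen presentation list at 0.21. These 4 had adjusted p = 0.207 with an estimated correlation. H2-Aa was at 1.63 ± 0.34 (adjusted p = 0.284), Cd74 at 145 against 520 CPM (1.85 ± 0.42, adjusted p = 0.367), and Xcr1, a receptor of conventional dendritic cells, at 1.67 ± 0.34 (adjusted p = 0.284). The other called lists had smaller medians: ribosomal proteins −0.21, respiratory chain −0.19, S phase −0.17 (−0.10 without KDM6B OE 3, −0.11 without double lesion 1), T and NK cells 0.17, innate immune 0.16 (0.27 without KDM6B OE 1, 0.10 without KDM6B OE 3), cytokine and chemokine receptors 0.15, lymphoid priming 0.13, TGF-beta 0.07 and MYC targets −0.07. The TGF-beta median was 0.04 without KDM6B OE 2, and 0.12 and 0.13 without double lesion 2 and 3, and the MYC median was −0.14 and −0.04 without KDM6B OE 1 and 2. Histones were at 0.15 (0.06, 0.24 and 0.23 without KDM6B OE 1, 2 and 3) and interferon response genes at 0.14 (0.01 without KDM6B OE 3, 0.03 and 0.08 without double lesion 2 and 3). The 5 sex-linked genes, 4 of them on the Y chromosome, were at 3.68, and no KDM6B OE library had Y-linked transcripts. Of the 19 lists called with the preset correlation none held with an estimated one (adjusted p = 0.207 to 0.683). Without Vav Cre 3, 2 antigen presentation genes rose. The count of genes was 5 without KDM6B OE 1 and 3 without Vav Cre 3. With the replicate number as a block it was 3, with array weights 92 and with only the compared groups 61.

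The double lesion against Tet2 KO asks what the transgene adds in Tet2-deficient cells, both groups carrying Cre. The test called 28 genes changed, 25 higher and 3 lower, of which 22 by 2-fold or more. Immediate early genes led again, with 12 of 30 rising, none falling and all 30 values positive (median 1.45, 24 adjusted over the list alone). This was the list whose call held with an estimated correlation (adjusted p = 0.0491; fry's adjusted p = 0.00256). Egr1 rose by 3.39 ± 0.39 (adjusted p = 0.00233), Klf2 by 3.18 ± 0.47, Dusp1 by 2.67 ± 0.34, Zfp36 by 2.60 ± 0.32 and Klf6 by 2.19 ± 0.22 (adjusted p = 0.00195). Jun rose by 1.67 ± 0.29, Btg2 by 1.60 ± 0.21, Ier2 by 1.47 ± 0.17 and Ier5 by 1.2 ± 0.13. Rhob, a small GTPase in the same list, rose by 1.68 ± 0.24. Ccl4 and Nfkbiz, the 2 of 35 innate immune genes that rose, did so by 2.02 ± 0.29 and 1.60 ± 0.27 (list median 0.24, 7 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation). Mcl1 rose by 0.76 ± 0.11 and with Btg2 made up the 2 of 28 p53 genes that rose, also 2 adjusted over the list alone (median 0.13; adjusted p = 0.478 with an estimated correlation). Fmnl3, a formin that shapes actin, rose from 9.46 ± 1.33 to 52.0 ± 8.27 CPM (2.34 ± 0.42, adjusted p = 0.0374). The haem synthesis gene Alas2, overlapped by Apex2, rose from 2.11 ± 0.651 to 11.5 ± 2.49 CPM (2.01 ± 0.36, adjusted p = 0.0366).

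The 3 lower genes were Cdca3 (141 ± 11.7 against 77.9 ± 12.3 CPM, −0.86 ± 0.14, adjusted p = 0.0291), Nusap1 (−0.92 ± 0.16, adjusted p = 0.0344) and the phosphatase inhibitor gene Anp32a (−0.96 ± 0.17, adjusted p = 0.0366). All 40 G2 and M phase genes had lower values than in Tet2 KO (median −0.57, or −0.39 without double lesion 1), of which 2 fell over all genes and 36 passed when adjusted over the list alone (adjusted p = 1.9e-28; adjusted p = 0.367 with an estimated correlation). Bub1 (−0.65 ± 0.12, adjusted p = 0.0577) and Mki67 (−0.68 ± 0.13, adjusted p = 0.058) did not pass. Ribosomal and respiratory chain genes both had a median of −0.28 (−0.16 and −0.18 without Tet2 KO 2) and S phase genes one of −0.17 (−0.09 without double lesion 1), with none past the test and adjusted p = 0.705 with an estimated correlation in all 3. The interferon list was at −0.16 (−0.03 without Tet2 KO 3, −0.07 without double lesion 1). The mast cell, basophil and eosinophil list was at 0.34 and the mature B cell list at 0.25 (0.69 without Tet2 KO 2, −0.20 without Tet2 KO 3, 0.14 without Tet2 KO 1 and 0.16 without double lesion 3). All 3 had adjusted p = 0.705 with an estimated correlation.

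edgeR called 20 genes here and DESeq2 146, and 21.6% of genes had groups without overlap, where chance gives 10% on average. The count was 52 and 55 without Vav Cre 2 and 3, 17 without KDM6B OE 1, 13 and 18 without Tet2 KO 1 and 3, and 13, 9 and 10 without double lesion 1, 2 and 3. It was 173 with array weights, 18 with a sex term and 53 with only the compared groups. The immediate early count was 7 without double lesion 2 or 3. The innate count was 1 without KDM6B OE 2, Tet2 KO 3 or double lesion 1 and 0 without Tet2 KO 1 or double lesion 2 or 3, and the p53 count was 1 without Tet2 KO 1 or 2 or any 1 double lesion library. The G2 and M phase count was 6 and 5 without Vav Cre 2 and 3, 0 without KDM6B OE 1, Tet2 KO 1 or 3, or double lesion 1 or 2, and 1 without any 1 of the others. Egr1, Dusp1, Zfp36, Klf6, Btg2, Ier2 and Ier5 kept their call under every alternative. Klf2 and Rhob were lost without double lesion 2 or 3 (adjusted p up to 0.0929 and 0.0720), and Ccl4 without Tet2 KO 1 or double lesion 2 or 3 (up to 0.0720). Mcl1 was lost without Tet2 KO 1 or 2 or any 1 double lesion library (up to 0.0948). Fmnl3 and Anp32a were lost without Vav Cre 1, KDM6B OE 1 or 2, or any 1 Tet2 KO or double lesion library (both up to 0.214). Alas2 was lost without KDM6B OE 1 or any 1 of these 6 libraries (up to 0.204). Jun was lost without Vav Cre 1, KDM6B OE 1 or 3, Tet2 KO 1 or 2, or any 1 double lesion library (up to 0.164). Nfkbiz was lost without KDM6B OE 2 or any 1 of the 6 (up to 0.139), Cdca3 without KDM6B OE 1 or any 1 of the 6 (up to 0.14). Nusap1 was lost without Vav Cre 1, any 1 KDM6B OE or Tet2 KO library, or double lesion 1 or 2 (up to 0.179). With a sex term Alas2, Anp32a and Fmnl3 were at adjusted p = 0.0745, Nusap1 at 0.0742, and Cdca3 and Nfkbiz at 0.0582. In edgeR Alas2 was at adjusted p = 0.1, Fmnl3 and Jun at 0.061, Nusap1 at 0.0569 and Anp32a at 0.0503, and with a pseudocount of 0.25 Alas2 was at 0.0614.

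The interaction asks whether the double lesion departs from the sum of the single lesions on the log2 scale, the cooperation named in the title of the series. Cre is part of this contrast. No gene passed in limma (smallest adjusted p = 0.753) or edgeR, DESeq2 called 5, and 578 genes had an unadjusted p under 0.05. The smallest p on the positive side belonged to Il1rl1 (1.87 ± 0.36, adjusted p = 0.753), Hist1h2an (1.69 ± 0.37), Hist1h2bb (1.65 ± 0.37) and Hist2h2bb (1.40 ± 0.33), the last 3 at adjusted p = 0.999. Il1rl1 stood at 9.61 CPM in Vav Cre, 2.35 in KDM6B OE, 3.40 in Tet2 KO and 4.02 in the double lesion. On the negative side were the collagen gene Col1a2 (−2.89 ± 0.57, adjusted p = 0.753), Pomt2, a protein mannosyltransferase overlapped by Gstz1 (−1.25 ± 0.23, adjusted p = 0.753), Uso1, a vesicle tether (−0.76 ± 0.16) and Fam171a1 (−0.86 ± 0.20), the last pair at adjusted p = 0.999. For Fos, Egr1 and the other immediate early genes the list median was −0.28 (adjusted p = 0.116), and 21 of 30 values were negative.

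The 3 comparisons with Vav Cre share their controls, so for overlaps among them the number expected for independent lists may be too low as a reference. Of the 68 genes higher in KDM6B OE, 66 were also called higher in the double lesion (4.99 expected for independent lists), and of the 10 lower ones 8 were (0.758 expected). The 3 genes higher in Tet2 KO and Tet2 itself were also called in the double lesion (0.22 and 0.0758 expected), and no gene was called in both single lesions. Of the 25 genes higher in the double lesion than in Tet2 KO, 20 were among the 68 (0.13 expected), and these 2 comparisons share no group, though they share the variance estimates of the fit. In 100 simulated draws without any change, no gene was shared between either single lesion and the double lesion. Each of these comparisons made calls in only 3 of the draws, so this says little about lists as long as the real ones. Where calls were made, they reached 618 genes for KDM6B OE, 615 for Tet2 KO and 2458 for the double lesion. A draw without any change thus called more genes than the 1947 of the double lesion. Log2 changes correlated over genes at r = 0.788 between KDM6B OE and the double lesion, 0.737 between Tet2 KO and the double lesion, and 0.655 between the single lesions. In 100 simulated draws, unchanged groups sharing controls gave a median of 0.558 (0.0457 to 0.882), a range that holds all 3 values. Those controls were drawn from the residuals of all 12 libraries, not from Vav Cre alone. The covariances were 0.146, 0.116 and 0.0843, with differences of 0.108, 0.0783 and 0.0462 from the simulated mean of 0.0381. All 3 lay above the simulated range of 0.00215 to 0.0799. Vav Cre spread more (median SD 0.28) than KDM6B OE, Tet2 KO and the double lesion (0.15, 0.21 and 0.15). The simulated covariances may therefore be too low, and the excess does not show a change beyond the shared controls. Of the 1947 genes called in the double lesion, 99.3% had the same sign in KDM6B OE and 97.9% in Tet2 KO, within the simulated ranges of 38.5% to 100% and 43.6% to 99.8% (medians 87.1% and 86.8%). Genes are not independent replicates, the 3 controls are too few to split, and part of the correlations, and of the overlaps between comparisons with Vav Cre, may come from the shared controls.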

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

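The tests on handling, on mature cells and on stem cells below were chosen after the results were seen. Among the fixed gene lists, 8 of 32 were called for the interaction, a difference between the effects of 1 lesion with and without the other, by camera with the preset correlation. Data without any change gave 8.98 such calls on average, and no list was called with an estimated correlation (adjusted p = 0.192 to 0.934 for the 8) or in fry, so no difference is shown and the medians are given as values. Replication-dependent histone genes had an interaction median of 0.72 on the log2 scale (adjusted p = 3.7e-16), with 27 of 30 values positive. Interferon response genes had −0.37 (adjusted p = 1.1e-06), with 38 of 40 values negative. Ribosomal protein genes had 0.16 (0.01 without Vav Cre 2, 0.27 without Vav Cre 3, 0.09 without Tet2 KO 1, 0.29 without Tet2 KO 2). The G2 and M phase list had −0.18 (−0.01 without double lesion 1, −0.28 without double lesion 2 or 3 or Tet2 KO 2, −0.27 without Vav Cre 2, −0.12 without KDM6B OE 3 and −0.10 without Tet2 KO 3). The dendritic cell list had 0.26 (0.16 without Tet2 KO 2), the T and NK cell list 0.26 (0.40 without Vav Cre 1, 0.42 without KDM6B OE 1) and the lymphoid priming list 0.21 (0.13 without Tet2 KO 2). The mature B cell list had 0.0888 and ranged from −0.18 without Tet2 KO 3 and −0.06 without Tet2 KO 1 to 0.58 without Tet2 KO 2 (0.34 and 0.14 without Vav Cre 1 and 2, 0.19 and 0.47 without KDM6B OE 1 and 2, and 0.19, 0.18 and 0.20 without double lesion 1, 2 and 3). No gene had a changed interaction in limma (578 at an unadjusted p under 0.05; 0 in edgeR, 5 in DESeq2).

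The first pattern weighed is the higher level of Fos, Egr1, Klf2 and other immediate early genes in both groups with the KDM6B transgene. Sex is argued against, with a list median of 1.52 in KDM6B OE with a sex term, and so are mature cells in the sort as the whole cause in KDM6B OE: against Tet2 KO the highest median of 6 lists of such cells was −0.130 and their highest upper limit 0.287, while the immediate early median was 1.45 (1.17 to 1.67). Handling that varied from library to library without regard to genotype stays open: the list mean was at least 1.38 in each of the 6 libraries with the transgene and at most 0.55 in the 6 without (exact permutation p = 0.00216), but this restates the pattern and decides nothing. Handling that differed between genotypes stays open too, since sorting days are not given and the heat-shock median was 0.468 in KDM6B OE (95% interval −0.161 to 1.21) and 0.0589 in the double lesion (−0.397 to 0.207), with 3 of the 8 heat-shock genes also in the immediate early list. In KDM6B OE against Vav Cre, tested first, mature cells stay open (highest median 0.272, mast cell and eosinophil genes up to 1.30). They do in the double lesion too (mast cell and eosinophil median 0.340 against Tet2 KO, 0.144 to 0.888). A transgene effect also stays open and cannot be told apart from group handling.

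The second pattern is the lower level of G2 and M phase genes such as Cdca3, Nusap1 and Top2a in the double lesion. Transcript length and GC content are argued against as the whole cause, since the median was −0.758 with their trend removed (95% interval −0.936 to −0.669). A single library is argued against as well, since the median closest to 0 was −0.659, without double lesion 1. A larger share of long-term stem cells, which divide rarely, stays open: their list had a median of 0.107 (95% interval −0.0436 to 0.324). The list was lower in the single lesions too, with medians of −0.42 in KDM6B OE and −0.28 in Tet2 KO against Vav Cre. The double lesion lay below them, at −0.50 against KDM6B OE and −0.57 against Tet2 KO. Slower division with both lesions may be a biological explanation and was not tested, since cell cycle was not measured apart from RNA.

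The third pattern is the lower level of ribosomal protein genes such as Rps2 and Rpl29 in the double lesion. Transcript length and GC content are argued against as the whole cause (median −0.523 with their trend removed, 95% interval −0.585 to −0.491). A single library is too (closest to 0 at −0.496, without Vav Cre 2), and so is the authors' scaling (closest to 0 at −0.587, rescaled to equal totals). A change in the share of nuclear RNA stays open and was not tested: the nuclear RNA Malat1, chosen after its values were seen, was at 3901 to 4595 CPM in the double lesion and at 1686 to 2313 CPM in Vav Cre. The lower level was not limited to the double lesion. Against the same Vav Cre libraries the list median was −0.46 in KDM6B OE and −0.39 in Tet2 KO. The double lesion lay below them, at −0.21 against KDM6B OE and −0.28 against Tet2 KO. Single Vav Cre libraries ran from −0.21 to 0.33 around their own mean, and whether these controls were unusual was not tested. An effect of either lesion or of the combined genotype on these genes may remain, as may a difference between sorts, and none was tested.

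Other splits of the same libraries were run for the count of genes changed. For 3 libraries against 3, 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 78 and 1 for KDM6B OE against Vav Cre (1 split as high, the real one), 1947 and 0 for the double lesion against Vav Cre (1 split), 28 and 0 for the double lesion against Tet2 KO (1 split), and 0 and 0 for the double lesion against KDM6B OE (10 of 10 splits). For Tet2 KO against Vav Cre they were 4 and 1504 (2 splits as high). That other split exchanges Vav Cre 3 and Tet2 KO 2. It points to a structure of the samples that runs across the groups, while Tet2 levels go with the labels (97.1 CPM in Vav Cre 3 and 24.9 CPM in Tet2 KO 2). Of its 1504 genes, 365 were also called in the double lesion against Vav Cre in the same direction (111 expected for independent lists) and 0 in the opposite one. Both put Vav Cre 1 and 2 on the same side, so part of this overlap may come from shared libraries. The genes of that split also had a similar bias, with median lengths of 5269 bp for higher and 2398 bp for lower genes (4940 and 2756 bp in the double lesion) and a median GC content of 55.0% and 47.6% (53.2% and 49.0%). For the interaction, 100 of 100 drawn splits gave at least the real count of 0 (highest other 317). Any split reaches a count of 0, so this says nothing on chance, and the same holds for the double lesion against KDM6B OE.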

How the results depend on the processing

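The sex term and the correction for length and GC were chosen after seeing the data, and the other alternatives were planned. Depth limits genes near 0, since 3 reads were worth at most 0.139 CPM. Where a library is left out, a group of 2 is assumed to vary like the others. Of 4067 alternative values for 171 gene results, 3620 kept their direction and side of the threshold, 351 lost the call, 92 gained it and 4 reversed. Genes changed in KDM6B OE against Vav Cre were 78, with 284 under the replicate block, 972 with array weights, 162 with a sex term, 119 with the length and GC trend removed, 22 with only the compared groups and 729 in DESeq2. Leaving out 1 library gave 22 (KDM6B OE 1) to 1934 (Vav Cre 3). Tet2 KO against Vav Cre had 4, with 1 under the replicate block, 11 with the length and GC trend removed, 0 with only the compared groups and 160 in DESeq2, and 1 (KDM6B OE 2) to 307 (Vav Cre 3) with a library left out; in limma 1760 genes had an unadjusted p under 0.05 and edgeR called 4. The double lesion against Vav Cre had 1947, with 289 with only the compared groups, and 304 (double lesion 1) to 3585 (Vav Cre 3) with a library left out. The replicate block gave 2699, array weights 2698, the sex term 1354 and the length and GC trend removed 1843, all within 1.5 times. The double lesion against KDM6B OE had 0 in limma and edgeR (771 at an unadjusted p under 0.05), with 3 under the replicate block, 92 with array weights, 61 with only the compared groups and 20 in DESeq2, and 0 (Vav Cre 1, for example) to 5 (KDM6B OE 1) with a library left out. The double lesion against Tet2 KO had 28, with 173 with array weights, 18 with a sex term, 53 with only the compared groups and 146 in DESeq2, and 9 (double lesion 2) to 55 (Vav Cre 3) with a library left out. The interaction had 0 in limma and edgeR (578 at an unadjusted p under 0.05) and 5 in DESeq2, and 0 with any library left out. Fixed gene lists called in the 6 comparisons, in the order above, were 9, 13, 14, 19, 10 and 8 with the preset correlation, 0, 0, 0, 0, 1 and 0 with an estimated one, and 4, 0, 9, 0, 2 and 0 in fry. For Tet2 KO against Vav Cre array weights gave 8 lists, and a library left out 6 (Tet2 KO 2) to 13. For the interaction a sex term gave 14. Reversed values were near 0. Tet2 in KDM6B OE against Vav Cre was at −0.05, with 0.0791 without Vav Cre 3, 0.0842 without KDM6B OE 1 and −0.19 without Vav Cre 2. Kdm6b in the double lesion against KDM6B OE was at 0.05, with −0.12 without KDM6B OE 2, −0.06 without double lesion 2 and 0.19 without KDM6B OE 1. The labels do not pair the libraries by replicate number, and the values leave it unsettled: 10 of 18 pairs with the same number correlated above 0.1 (r from −0.149 to 0.388), all 6 pairs of replicate 1 among them (0.158 to 0.388), and 8 of 12 libraries correlated best with their own number. The block gives the values under pairing. The cause of these changes was not tested.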

Other observations

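The genes in this part were chosen after their values were seen, and none of the lists in the next sentences was called in a comparison. Long-term stem cell genes (37 tested) had a median of 0.17 in KDM6B OE, 0.11 in Tet2 KO and 0.11 in the double lesion against Vav Cre. HOX cluster genes and partners had 0.25, 0.10 and 0.07, genes of the H3K27 methylation machinery 0.09, 0.06 and 0.18, and genes of the DNA methylation machinery 0.05, 0.02 and 0.06. Some single members of the stem cell list were called higher in the double lesion. The transcription factor genes Meis1, Gata2 and Hlf rose by 0.64 ± 0.16, 0.67 ± 0.18 and 0.68 ± 0.19. Gata2 is also in the mast cell, basophil and eosinophil list, whose mean log2 difference from Vav Cre was 1.27 ± 0.40 there. Its rise can therefore not be assigned to stem cells. Meis1 was lost without Vav Cre 2 or double lesion 1 or 3 (limma's adjusted p up to 0.0974), Gata2 without Vav Cre 2 or any 1 double lesion library (up to 0.122), and Hlf without the same libraries (up to 0.135). Ezh2, the methyltransferase that opposes KDM6B, fell by 0.51 ± 0.11, and Phf1, a partner of it, rose by 1.03 ± 0.28. Ezh2 was lost without double lesion 1 (adjusted p = 0.0706) and Phf1 without Vav Cre 2 or any 1 double lesion library (up to 0.121). With only the compared groups in the fit Ezh2, Gata2, Meis1 and Phf1 were at adjusted p = 0.0697, 0.0999, 0.0575 and 0.0871. With array weights Gata2, Hlf and Phf1 were at 0.0554, 0.0510 and 0.0501, and Gata2 was also lost with a sex term (0.0502) or with the length and GC trend removed (0.0987). Dnmt3a was at 0.87 ± 0.29 and did not pass (adjusted p = 0.0556).

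The MYC target and ribosome biogenesis list was not called in the double lesion (median −0.17, adjusted p = 0.0561, with 1 of 38 members rising and 5 falling). Myc itself rose by 0.61 ± 0.14 and was lost without Vav Cre 2 or double lesion 2 (adjusted p = 0.0529 and 0.0569). The cyclin-dependent kinase gene Cdk4 fell by 0.58 ± 0.11, the nucleolar gene Npm1 by 0.67 ± 0.15 and the glycolytic gene Gapdh by 0.78 ± 0.13, while the glucose transporter gene Slc2a3 rose by 1.13 ± 0.18. Npm1 was lost without double lesion 1 (adjusted p = 0.0777). The adhesion gene Vcam1 rose from 6.79 to 31.3 CPM (2.21 ± 0.42, adjusted p = 0.00809). Lists not called in the double lesion included glycolysis (median 0.11), the unfolded protein response (−0.07), adhesion and migration (0.19), erythroid genes (−0.15), megakaryocyte priming (0.00), and endothelial and stromal markers (−0.09 and 0.23). Pf4, a platelet chemokine gene, fell by 1.04 ± 0.32 and was lost without Vav Cre 1 or 2, any 1 KDM6B OE library, or double lesion 1 or 2 (adjusted p up to 0.183). With only the compared groups in the fit Myc, Npm1 and Pf4 were at adjusted p = 0.0568, 0.0638 and 0.0770. Pf4 was also lost with the length and GC trend removed (0.124), with a sex term (0.0717), in edgeR (0.0506) and rescaled to equal totals (0.0530).

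Epx, an eosinophil peroxidase gene, was at 41.0 CPM in Vav Cre and 510 CPM in the double lesion (5.36 ± 1.29, adjusted p = 0.0195) and was lost without Vav Cre 2 or double lesion 1 or 2 (adjusted p up to 0.0989). Xcr1, a dendritic cell receptor gene, rose from 2.02 to 8.53 CPM (1.66 ± 0.34, adjusted p = 0.0103). Cd74 rose by 1.36 ± 0.42, with 503 to 554 CPM in the double lesion, and was lost without Vav Cre 2 or 3, any 1 KDM6B OE library or any 1 double lesion library (adjusted p up to 0.127). The lymphoid enzyme gene Dntt fell by 0.88 ± 0.27, and was lost without Vav Cre 1 or 3, any 1 KDM6B OE library, Tet2 KO 3 or any 1 double lesion library (adjusted p up to 0.125). Igll1, of the surrogate light chain, was at 0.0152 CPM in Vav Cre and 3.99 CPM in the double lesion, and was lost without Vav Cre 2 or double lesion 1 or 3 (adjusted p up to 0.124). Epx was also lost with array weights (0.0815), with only the compared groups (0.0685), in edgeR (0.0963) and in DESeq2 (0.0681), and Igll1 with only the compared groups (0.0810). Cd74 was lost in edgeR (0.0723), in DESeq2 (0.0948), with a sex term (0.0685) and without a filter (0.0511). Dntt was lost with the length and GC trend removed (0.144), rescaled to equal totals (0.0777), with only the compared groups (0.0594) and without a filter (0.0540). In Tet2 KO 2 the B cell genes Cd79a and Ms4a1 were at 49.8 and 16.0 CPM, against 1.95 to 16.8 and 0.351 to 8.21 CPM in the other 11 libraries.

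Part of the spread between libraries ran along a first component with 31.9% of the variance. Vav Cre 2 lay at −53.7 on it, Vav Cre 1 and Tet2 KO 2 at −22.6, Vav Cre 3 at −7.11 and double lesion 1 at 31.2. Double lesion 2 and 3 lay at 19.1 and 17.4, KDM6B OE 1, 2 and 3 at 16.0, 8.85 and 3.49, and Tet2 KO 1 and 3 at 8.82 and 0.932. All Vav Cre libraries were thus negative and all KDM6B OE and double lesion libraries positive, so this component also runs with genotype. Array weights were lowest for Vav Cre 3 (0.299), Vav Cre 2 (0.329) and Tet2 KO 2 (0.415).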
